A study of Mus musculus with 12 samples.

How the data were processed

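RNA was measured in alveolar macrophages of 12 C57Bl/6 mice on Illumina Mouse WG-6 v2 BeadChips, a bead array with 45281 probes, with 1 array per mouse. Alveolar macrophages are the phagocytes of the airspaces. They were recovered by lavage of the lungs 60 days after an oropharyngeal dose of vehicle (35% surfactant in saline, 6 control mice) or of 100 µg of multiwalled carbon nanotubes (MWCNT) in the same vehicle (6 mice). Per the labels, the cells were over 90% pure, each array held the RNA of a separate animal, and biotin was the label. The labels used here give no sex.

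The deposited scanner table holds, per the file headers, 1 signal and 1 detection p-value for each probe and array. Its intensity values are on a linear scale, without background subtraction and without normalization between arrays as deposited, since their medians differ. The deposited detection p-value compares a probe with the negative-control beads of its own array. The authors' processed intensity values were made with lumi, per the submitters' processing notes; its version and settings are not given in the sources used here. In that matrix the sorted values of the 12 arrays differed by 0.0288% (median over ranks), as quantile normalization leaves them. The scale was linear, the lowest value was 200.3, and the median of each column was 227.8. Each column had a rank correlation of 1.00 with the scanner signal of its own array, higher than with any other array, on 12 of 12 arrays. Where the offset of about 200.3 comes from stays unknown, and the columns were not centred by gene.

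Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Probes with several or no symbols are unnamed here. The symbols stand for 19057 genes.

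The scanner values were processed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The neqc function removed background, with negative controls inferred from the detection p-values, added an offset of 16, normalized by quantiles and took log2. A probe was kept where its detection p was under 0.05 on at least 3 of the 12 arrays, which left 19291 probes. Each gene was represented by its kept probe with the highest mean, giving 10143 named genes and 3067 unnamed probes, 13210 features in all. MWCNT and control arrays were compared by lmFit and eBayes without covariates, with two-sided tests and Benjamini-Hochberg adjustment over the 13210 features. A gene was called changed at an adjusted p under 0.05. Fold changes are log2 MWCNT minus control with the SE of the fit, and levels are normalized log2 intensities with the SD over 6 arrays.

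A gene detected on no array of a group was treated as not well above background there. Its fold is then a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among detected probes and the probe's own signal.

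Gene lists for pathways and for markers of cell types the lavage might hold were fixed in number at 32, and 601 of their 656 different genes were matched to a symbol on the array. Lists with at least 5 measured members, 29 of them, were tested by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these 29. The camera test compares a list with all other features. Camera with a correlation estimated for each list, and fry, which tests whether a list moved from no change and compares it with no other genes, were alternatives. Every list's result is given in the text. A list score is the mean over the measured members of each array's log2 difference from the control mean.

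The genes named are those with the 10 largest increases and 10 largest decreases among changed genes, leaving out clone and predicted names. From each list they include up to 4 members with the smallest adjusted p and the brightest member that did not pass. Mmp12, Spp1, Pparg, Abcg1, Abca1, Cd36, Twist1, Ccl2, Tnf, Il1b, Arg1, Chil3 and Siglecf are named whether they passed or not. The test, the probe filter, the lists, this rule and the alternatives of background correction, normalization, filter, probe rule, variance model, array weights, size of change, replicate block and leaving out each array were chosen before the data were examined. Leaving out the arrays with Y-linked signal, sex as a covariate, scaling to the median of the kept probes, leaving out a pair of arrays that stood apart, and the grouping of genes into families were added after seeing the data. Array measures were compared by exact permutation tests in Python 3.11.15 with SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

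The limma test and camera were run on simulated normalized values with 13210 features, the spread of these arrays and 6 arrays per group. Background correction, scaling between arrays, the probe filter and the choice of probes were not tested this way. The simulated features varied independently, and 220 were changed. The limma test called 65% of features changed by a log2 of 0.5, 97.5% of those changed by 1 and 97.5% of those changed by 2. It called 57.5% of features changed by -0.5 and 95% of those changed by -1. Of 188 calls, 13 (6.91%) were false. The number of arrays limits the precision. The slide was not used as a batch because the files used here name no slide. Where slides followed the groups, their effect could not be told apart from that of MWCNT.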

Results

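The arrays compared alveolar macrophages from 6 mice given multiwalled carbon nanotubes (MWCNT) with those from 6 vehicle controls at day 60, in a mouse model of chronic granulomatous inflammation that the study set beside human sarcoidosis. MWCNT are rigid, poorly degradable fibres that macrophages take up. Correlations between arrays of a group over all features ranged from 0.986 to 0.994 among controls and from 0.984 to 0.993 among MWCNT arrays. The share of probes detected was 38.5% ± 0.469 (SD, n = 6) in controls and 39.8% ± 0.592 with MWCNT (exact two-sided permutation p = 0.00433, adjusted p = 0.00866 over 4 measures). The background signal was 135 ± 6.16 and 154 ± 9.72 (exact p = 0.00433, adjusted 0.00866), and the median signal 147 ± 7.60 and 169 ± 11.7 (exact p = 0.0108, adjusted 0.0144). The 95th percentile of signal lay 18.1 ± 1.76 times above background in controls and 18.4 ± 1.53 times with MWCNT (exact p = 0.714).

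MWCNT macrophages carried more transcript of Mmp12, the macrophage elastase, which rose 9.83-fold from 7.60 ± 0.30 to 10.90 ± 0.53 on the log2 scale (log2 fold change 3.30 ± 0.22 SE, n = 6 per group, adjusted p = 3.72e-06). Arg1, which encodes the arginine-degrading enzyme of alternatively activated macrophages, was not well above background on any control array and was at least 9.74-fold higher with MWCNT (adjusted p = 0.000206). Cidec, which encodes a lipid droplet protein, fell by 0.58 ± 0.07 on the log2 scale (adjusted p = 0.000243). Pparg, the lipid-sensing nuclear receptor, differed by -0.12 ± 0.10 (adjusted p = 0.484). In limma's test 1297 of 10143 named genes changed (12.8%), 759 raised and 538 lowered.

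Raised genes moved further than lowered ones. At least 2-fold changes numbered 278 raised and 5 lowered, or 233 and 5 with genes below background at their bound. The median log2 fold change was 0.75 for raised genes (0.60 with bounds) and -0.42 for lowered genes (-0.40 with bounds). Every MWCNT array lay above every control array for 426 of the raised genes, and below for 243 of the lowered ones. Over all named genes these shares were 4.41% and 2.59%, and chance gives 0.108% each way. Of the raised genes 180 were detected on no control array, and 34 lowered genes on no MWCNT array. The size of these medians moved with the normalization: 0.37 and -0.26 without background correction, 0.53 and -0.32 with normexp, 0.90 and -0.28 with median scaling, and 0.28 and -0.21 in the authors' values. Mmp12 rose by 2.64 without background correction and 2.28 in the authors' values, Arg1 by 1.99 and 1.34, and Tgfb2 fell by 0.41 and 0.23, each still called. Among 3067 unnamed probes, 163 were raised and 240 lowered. Another kept probe of opposite sign was present for 76 changed genes, and for 2 of them it was called in the opposite direction.

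The 10 largest increases included 6 genes that were not well above background in controls. Besides Arg1 these were Npy, which encodes a neuropeptide (at least 9.20-fold, adjusted p = 4.55e-05), Retnla, a secreted protein of alternative activation (at least 7.09-fold, adjusted p = 0.00118), and S100a9, a calcium-binding protein of neutrophils and monocytes (at least 6.29-fold, adjusted p = 3.72e-06). Fcmr, the IgM Fc receptor, was at least 6.99-fold higher and was detected on 5 of 6 MWCNT arrays (adjusted p = 0.00289). Its fitted log2 fold change was 3.65, and 4.29 without MWCNT array 5. In the authors' values Fcmr rose by 1.23 and Arg1 by 1.34 on the log2 scale, so these bounds hold only for the processing used here. Sox7, a transcription factor, was at least 5.52-fold higher (adjusted p = 0.00153), though its 3 probes gave log2 fold changes of 3.33, 2.00 and -0.18. Syngr1 rose 12.8-fold (adjusted p = 6.93e-05), with 5 of 6 control arrays detecting it. Cd163l1, a scavenger receptor family member, rose 8.58-fold (adjusted p = 0.000281) and was detected on 1 control array. Trbv13-2, a variable segment of the T cell receptor beta chain, rose 8.12-fold (adjusted p = 0.000156) and was detected on 5 control arrays.

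Among the largest decreases, Tgfb2, a transforming growth factor, fell by 1.09 ± 0.12 on the log2 scale (adjusted p = 9.85e-05), and Il7, a lymphocyte growth factor, fell by 1.01 ± 0.17 (adjusted p = 0.00171). Apcdd1, an inhibitor of Wnt signalling, fell by 0.99 ± 0.12 (adjusted p = 0.000127), Ric3 by 0.97 ± 0.13 (adjusted p = 0.000287) and Clcf1, a cytokine of the interleukin-6 family, by 0.95 ± 0.10 (adjusted p = 8.31e-05). The class I related genes H2-Q1 and H2-M10.1 fell by 1.08 ± 0.12 and 1.02 ± 0.13, each detected on 1 MWCNT array (adjusted p = 6.93e-05 and 0.000221). Nacad and Hmcn1 were detected on no MWCNT array and were at least 1.46-fold and 1.51-fold lower (adjusted p = 0.000187 and 0.00347). Itgad, the integrin alpha D chain, fell by 1.11 ± 0.33 (adjusted p = 0.0394). Its level was 7.73 on MWCNT array 3 and at least 9.62 on the other MWCNT arrays. The Itgad call was lost without any 1 of control arrays 1, 2, 4, 5 and 6 or MWCNT arrays 1 and 2 (adjusted p from 0.0566 to 0.0759), with no filter on dim probes (0.0733) and with trend and robust variances (0.0620).

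**Figure D1:**
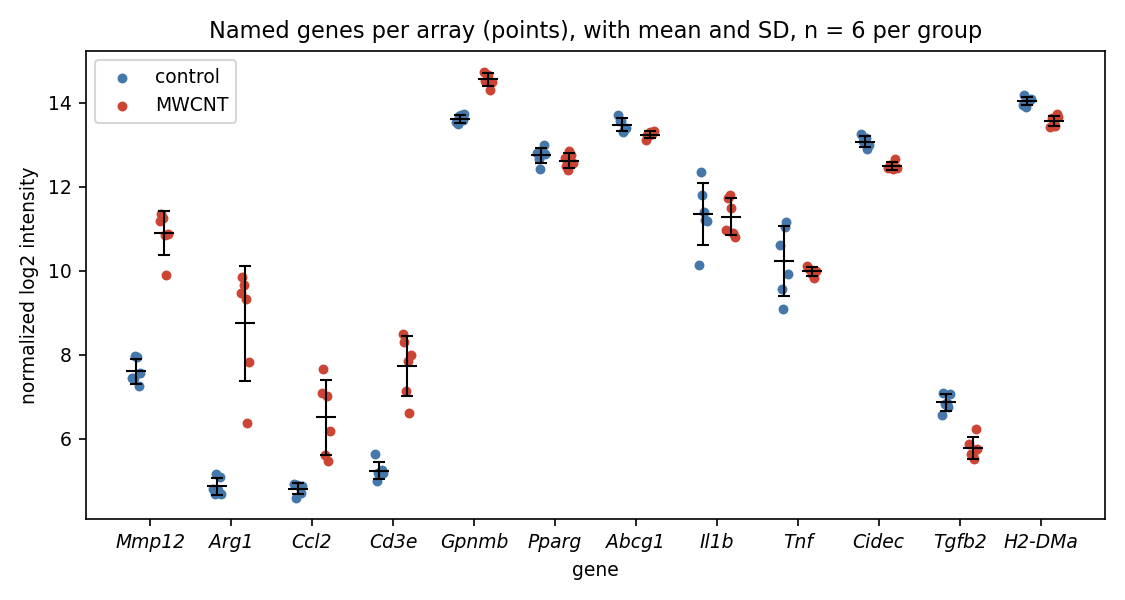
Normalized log2 intensity (vertical axis) of 12 named genes on each array, with points for single arrays and bars for the mean and SD of 6 control (blue) and 6 MWCNT (red) arrays. Mmp12 lay at 10.90 ± 0.53 with MWCNT against 7.60 ± 0.30, and the ranges of Pparg, Il1b and Tnf overlapped.

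Genes for matrix degradation rose as a group. Of 16 measured matrix proteases and inhibitors 8 rose, none fell and 8 were not called (12 raised and none lowered adjusted over the list alone). The median log2 fold change was 0.48 (0.45 with bounds), camera adjusted p = 2.54e-09, and adjusted p = 0.0432 with an estimated correlation. Besides Mmp12, Mmp14, a membrane-bound collagenase, rose by 1.94 ± 0.28 (adjusted p = 0.000557), and the gelatinase Mmp2 was at least 2.46-fold higher (adjusted p = 0.000503), while Timp2 differed by -0.10 ± 0.12 (adjusted p = 0.648). The score of this list was 0.93 ± 0.24 on MWCNT arrays, and that of T and NK cell markers was 1.33 ± 0.46 on the same arrays. Of 15 cathepsins and their inhibitors 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.16, camera adjusted p = 0.00237, adjusted p = 0.0645 with an estimated correlation). The collagen-degrading protease Ctsk rose by 0.88 ± 0.08 (adjusted p = 2.30e-05) and the lysosomal protease Lgmn by 0.54 ± 0.09 (adjusted p = 0.00171). The cathepsin median became -0.04 and the call ended when arrays were scaled to the median of the kept probes (adjusted p = 0.166); it also ended with median scaling (0.156; 5 raised and none lowered).

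Lysosomal genes moved little. Of 27 measured, 4 rose and none fell (4 and none adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.00996; adjusted p = 0.116 with an estimated correlation), which became -0.10 with scaling to the kept probes (4 raised and 5 lowered, adjusted p = 0.864). Median scaling also ended the call (adjusted p = 0.544). The tetraspanin Cd63 rose by 1.25 ± 0.12 (adjusted p = 5.20e-05) and Npc2, a cholesterol carrier, by 0.44 ± 0.08 (adjusted p = 0.00205). Of 16 macrophage fusion genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.00234, adjusted p = 0.0645 with an estimated correlation). Both scalings ended the fusion call (adjusted p = 0.0725 with median scaling and 0.0830 with the kept probes), with 7 raised and none lowered, and 5 raised and 4 lowered.

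Markers of monocyte-derived macrophages rose. Of 21 measured, 14 rose, none fell and 7 were not called (14 raised and 2 lowered adjusted over the list alone), with a median of 0.74 (0.63 with bounds), camera adjusted p = 1.08e-08 and adjusted p = 0.0432 with an estimated correlation; 12 rose and 3 fell with scaling to the kept probes. The complement subunits C1qb, C1qc and C1qa rose by 1.91 ± 0.19, 1.82 ± 0.19 and 1.56 ± 0.24 (adjusted p = 5.58e-05, 6.87e-05 and 0.000947). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 0.94 ± 0.08 (adjusted p = 2.30e-05) and the lipid receptor Trem2 by 0.86 ± 0.16 (adjusted p = 0.00322). The other, dimmer kept probes of Gpnmb rose by 1.25 to 1.68. F13a1, a coagulation factor subunit, was at least 1.26-fold higher and was detected on 5 MWCNT arrays (adjusted p = 0.00024). Lyz1, a lysozyme, differed by -0.09 ± 0.07 (adjusted p = 0.427), but was called raised by 0.43 with the mean of its probes (adjusted p = 0.0167) and lowered by 0.40 with scaling to the kept probes (0.00547). T and NK cell markers were raised on the same 6 arrays as these markers.

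Camera did not call the markers of resident alveolar macrophages. Of 14 measured, 2 rose, 2 fell and 10 were not called (2 and 2 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.589), though camera called the list lowered with median scaling (adjusted p = 0.0274). With scaling to the kept probes none rose, 6 fell and the median was -0.31 (adjusted p = 0.0537), and under the other 3 normalizations the adjusted p was 0.530 to 0.547. The fry test asks another question, whether a list moved from no change, and called this list (adjusted p = 0.00485). The keratin Krt79 fell by 0.52 ± 0.08 (adjusted p = 0.000631). The carbonic anhydrase Car4 rose by 0.36 ± 0.09 (adjusted p = 0.0179), a call that ended with scaling to the kept probes. Chil3, a secreted chitinase-like protein, differed by -0.08 ± 0.06 (adjusted p = 0.431; called lowered, -0.36, with scaling to the kept probes, 0.00574). Siglecf, Cd36 and Abca1 were not well above background on any array, and Spp1, which matched no probe by name, was not analysed here. Of 17 alternative activation genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 0.000542, adjusted p = 0.0981 with an estimated correlation and 0.0661 with probes detected on all 12 arrays; 6 raised and 4 lowered, median 0.09, with scaling to the kept probes, and 7 and none with median scaling). Besides Arg1 and Retnla, the lectin Mgl2 rose by 1.37 ± 0.15 (adjusted p = 6.87e-05), and the decoy receptor Il1r2 was at least 1.55-fold higher (adjusted p = 5.20e-05). Of these 17 genes 5 were also in another list, Il1r2 among them as a neutrophil marker, and neutrophil markers rose on the same arrays. Of 9 complement genes 3 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.47, camera adjusted p = 0.009998, adjusted p = 0.0645 with an estimated correlation; 4 raised and none lowered with median scaling).

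Chemokine genes rose as a group. Of 21 chemokines and receptors 15 rose, 1 fell and 5 were not called (16 and 1 adjusted over the list alone), with a median of 0.98, camera adjusted p = 1.55e-11 and adjusted p = 0.0645 with an estimated correlation. Ccl5, which attracts T cells, rose by 1.71 ± 0.19 (adjusted p = 7.29e-05), Ccl17 by 1.31 ± 0.13 (adjusted p = 5.45e-05) and Cxcl16 by 1.19 ± 0.13 (adjusted p = 8.58e-05). The monocyte attractant Ccl2 was at least 2.05-fold higher (adjusted p = 0.00342), and Cxcr4 differed by 0.08 ± 0.16 (adjusted p = 0.802). The chemokine score on MWCNT arrays was 0.91 ± 0.29, beside 1.33 ± 0.46 for T and NK cell markers. Of 23 interferon-stimulated genes 10 rose and none fell (14 and none adjusted over the list alone), with a median of 0.54, camera adjusted p = 1.08e-08 and adjusted p = 0.140 with an estimated correlation. Usp18, a brake on interferon signalling, rose by 2.16 ± 0.37 (adjusted p = 0.00191; 4 control arrays detected it), and the antiviral gene Oasl2 by 1.77 ± 0.30 (adjusted p = 0.00159).

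Of 19 inflammatory cytokine and NF-kB genes 2 rose, 2 fell and 15 were not called (2 and 2 adjusted over the list alone), with a median of -0.07 and a mean of 0.02 (camera adjusted p = 0.840). With scaling to the kept probes 2 rose and 4 fell (median -0.19), and with median scaling 3 rose and none fell (0.01). Tnf and Il1b differed by -0.26 ± 0.30 and -0.06 ± 0.31 (adjusted p = 0.633 and 0.928). Csf1, the macrophage growth factor, was at least 2.40-fold higher (adjusted p = 6.87e-05) and Il1a rose by 0.92 ± 0.17 (adjusted p = 0.00352). Tgfb1 fell by 0.35 ± 0.08 (adjusted p = 0.0135) and the receptor Tlr2 by 0.26 ± 0.06 (adjusted p = 0.0124), and both calls ended with median scaling (0.151 and 0.0735). The Tgfb1 call also ended without the 2 arrays with Y-linked signal (-0.27, adjusted p = 0.0591). Of 19 granuloma and sarcoidosis genes 8 rose and none fell (10 and 3 adjusted over the list alone), with a median of 0.26, camera adjusted p = 0.000672 and adjusted p = 0.0645 with an estimated correlation. Of these, 8 rose and 5 fell with scaling to the kept probes. Slc11a1, a phagosomal metal transporter, rose by 1.44 ± 0.15 (adjusted p = 6.87e-05), and its other, dimmer kept probes by 1.97 to 2.00. The cholesterol exporter Abcg1 differed by -0.24 ± 0.08 (adjusted p = 0.0618; -0.27 and 0.0478 without control array 4, and up to 0.125 without another array). It was called lowered without background correction (-0.23, adjusted p = 0.0317), with normexp (-0.24, 0.0439), in the authors' values (-0.25, 0.0316), with trend and robust variances (0.0203) and with scaling to the kept probes (-0.40, 0.00484), but not with median scaling (-0.20, 0.281). Twist1, a transcription factor detected on 2 control arrays and 1 MWCNT array, differed by -0.42 ± 0.14 (adjusted p = 0.0624; -0.49 without control array 6 or without MWCNT array 2, with adjusted p = 0.0363 and 0.0345; -0.57 and 0.00725 with scaling to the kept probes).

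Markers of lymphocytes rose on all 6 MWCNT arrays. Of 20 T and NK cell markers 14 rose, 1 fell and 5 were not called (15 and 2 adjusted over the list alone), with a median of 1.59 (1.48 with bounds), camera adjusted p = 1.55e-11 and adjusted p = 0.0645 with an estimated correlation. Scaling to the kept probes gave 13 raised and 2 lowered, and median scaling 15 and none. All 6 control arrays detected 8 of these 20 markers. Il7r, the interleukin-7 receptor, rose by 2.38 ± 0.21 (adjusted p = 3.10e-05), Cd3e, a chain of the T cell receptor complex, by 2.49 ± 0.27 (adjusted p = 7.29e-05; detected on 1 control array) and Icos, a T cell costimulator, by 1.78 ± 0.19 (adjusted p = 6.87e-05). Of 9 B and plasma cell markers 7 rose and none fell (8 and none adjusted over the list alone), with a median of 1.72 (1.05 with bounds), camera adjusted p = 6.53e-07 and adjusted p = 0.0981 with an estimated correlation. All 6 control arrays detected 2 of these 9. Cd79b, a chain of the B cell receptor, was at least 4.29-fold higher and Blk, a B cell kinase, at least 3.27-fold higher, each detected on 5 MWCNT arrays (adjusted p = 0.00399 and 0.00499). Among MWCNT arrays, array 5 had the lowest score for both lists.

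**Figure D2:**
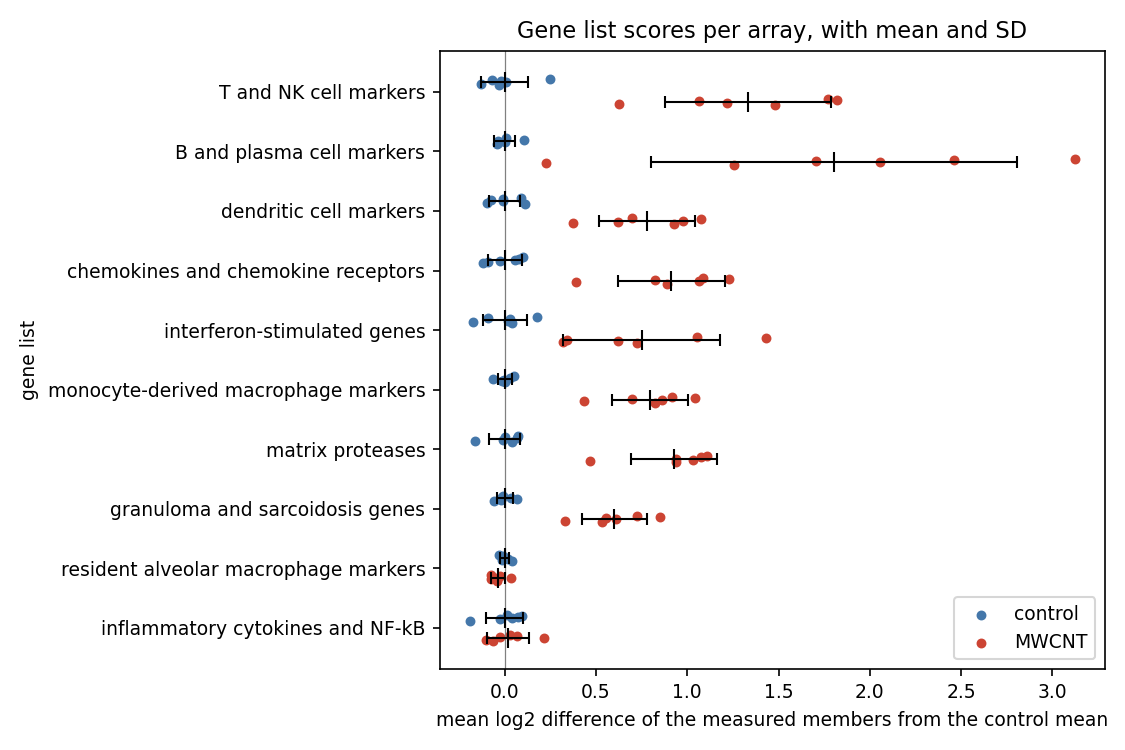
Score of 10 gene lists on each array (horizontal axis: mean log2 difference of the measured members from the control mean), with points for single arrays and bars for the mean and SD of 6 control (blue) and 6 MWCNT (red) arrays. The T and NK cell marker score ran from 0.63 to 1.82 on MWCNT arrays and from -0.13 to 0.25 on control arrays, while the resident macrophage score was -0.04 ± 0.04 with MWCNT.

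Markers of other cells also differed. Of 11 dendritic cell markers 8 rose and none fell (8 and none adjusted over the list alone; median 1.24, camera adjusted p = 1.59e-06, adjusted p = 0.0645 with an estimated correlation), with Itgae raised by 1.24 ± 0.18 (adjusted p = 0.000567). Of 7 neutrophil markers 4 rose and none fell (4 and none adjusted over the list alone; median 0.99, or 0.63 with bounds; camera adjusted p = 0.000324, adjusted p = 0.0645 with an estimated correlation), with S100a8 raised by 1.27 ± 0.18 (adjusted p = 0.000439). Of 16 lung epithelium markers 4 rose and none fell (4 and 1 adjusted over the list alone; median 0.21, or 0.14 with bounds; camera adjusted p = 0.0262, adjusted p = 0.401 with an estimated correlation). Scgb1a1, the club cell secretory protein, rose by 2.23 ± 0.53 (adjusted p = 0.0135). The epithelial call was lost with median scaling (adjusted p = 0.0784), probes detected on all 12 arrays (0.205), array weights (0.0591), and without any 1 of control arrays 1 and 2 or MWCNT arrays 2 and 3 (adjusted p up to 0.119). Scaling to the kept probes gave 4 raised and 1 lowered, and fry did not call a move from no change (adjusted p = 0.103). Of 6 endothelium and fibroblast markers 1 rose and none fell (3 and none adjusted over the list alone; median 0.30, or 0.21 with bounds; camera adjusted p = 0.00994, adjusted p = 0.140 with an estimated correlation). Without the 2 arrays with Y-linked signal 4 of these rose, with median scaling 3 (median 0.49) and with scaling to the kept probes 2. The proteoglycan Dcn was at least 1.18-fold higher and was detected on 4 MWCNT arrays (adjusted p = 0.00122). With under 5 measured members, the remaining marker lists were not tested as lists. Of 2 eosinophil and mast cell markers 1 rose, the histamine-forming enzyme Hdc by 1.76 ± 0.25 (adjusted p = 0.000527). None of 3 erythroid markers and none of 2 sex-linked genes was called.

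Lipid genes went in both directions. Of 21 PPARg and lipid handling genes 6 rose and 2 fell (8 and 3 adjusted over the list alone; median 0.01, camera adjusted p = 0.138, while fry called a move from no change with adjusted p = 0.0262). With scaling to the kept probes 6 rose and 5 fell (median -0.06), and with median scaling 7 rose and 1 fell (median 0.14). The scavenger receptor Msr1 rose by 1.08 ± 0.20 (adjusted p = 0.00268) and the fatty acid carrier Fabp5 by 0.92 ± 0.12 (adjusted p = 0.000206), while Cidec fell and the lipase Lpl differed by -0.02 ± 0.06 (adjusted p = 0.894; -0.32 and 0.00714 with scaling to the kept probes). Of 16 cholesterol synthesis genes 1 rose and none fell (1 and none adjusted over the list alone; median 0.01, camera adjusted p = 0.452). Camera called that list raised without the 2 arrays with Y-linked signal (median 0.15, adjusted p = 0.0436) and with sex as a covariate (0.0377). With median scaling 3 rose and none fell (median 0.17), and with scaling to the kept probes 1 rose and 1 fell (-0.03). Of 17 fibrosis and tissue repair genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Pdgfa, a growth factor for fibroblasts, raised by 2.68 ± 0.27 (adjusted p = 5.20e-05) and Igf1 by 1.62 ± 0.24 (adjusted p = 0.000681). The fibrosis median of 0.10 (camera adjusted p = 0.0420, adjusted p = 0.0981 with an estimated correlation) became -0.08 with scaling to the kept probes (0.355; 3 raised and 4 lowered). Its call also ended with median scaling (0.466; 5 and none), without background correction (0.0533), in the authors' values (0.0779), with either stricter probe filter (0.138 and 0.105), with array weights (0.0511) and without control array 1 or 3 or MWCNT array 1 or 2 (adjusted p up to 0.0697).

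Antigen presentation genes were mixed. Of 14 MHC class II presentation genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.03, camera adjusted p = 0.175). Scaling to the kept probes gave 3 raised and 5 lowered (median -0.08), and median scaling gave a median of 0.12. The costimulator Cd40 rose by 1.75 ± 0.20 (adjusted p = 9.85e-05) and H2-Ob by 1.79 ± 0.31 (adjusted p = 0.00189; detected on 2 control arrays). The peptide exchange chain H2-DMa fell by 0.47 ± 0.08 (adjusted p = 0.00131), and Cd74 differed by -0.03 ± 0.08 (adjusted p = 0.856; -0.29 and 0.0262 with scaling to the kept probes). Of 17 MHC class I presentation genes 2 rose and none fell (2 and none adjusted over the list alone), the transactivator Nlrc5 by 0.78 ± 0.17 (adjusted p = 0.00752) and H2-K1 by 0.54 ± 0.12 (adjusted p = 0.0112). The class I median of 0.11 (camera adjusted p = 0.0420, adjusted p = 0.230 with an estimated correlation) became -0.03 with scaling to the kept probes (0.614; 2 raised and 1 lowered). Its call also ended with median scaling (0.544) and without any 1 of control arrays 1, 4 and 6 or MWCNT arrays 1, 2, 3 and 4 (adjusted p up to 0.127).

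Of 24 cell cycle genes 6 rose and none fell (6 and none adjusted over the list alone; median 0.21, camera adjusted p = 9.72e-05, adjusted p = 0.154 with an estimated correlation), with Rrm2, which makes deoxyribonucleotides, raised by 0.45 ± 0.09 (adjusted p = 0.00401). Without the 2 arrays with Y-linked signal, which had the highest scores of this list (0.28 and 0.35), 1 cell cycle gene rose and the list stayed called (median 0.17, adjusted p = 0.00494). With median scaling 11 cell cycle genes rose (median 0.33). Of 21 NRF2 and antioxidant genes 5 rose and none fell (5 and none adjusted over the list alone; median 0.11, camera adjusted p = 0.00906, adjusted p = 0.0645 with an estimated correlation), with the cystine transporter Slc7a11 raised by 0.89 ± 0.18 (adjusted p = 0.00472). The NRF2 median became -0.05 with scaling to the kept probes, 3 rose and 4 fell, and the call ended (adjusted p = 0.411; 0.367 with median scaling). Without the arrays with Y-linked signal 2 NRF2 genes and 1 unfolded protein response gene rose. Of 18 unfolded protein response genes 3 rose and none fell (3 and none adjusted over the list alone; median 0.12, camera adjusted p = 0.0387, adjusted p = 0.141 with an estimated correlation). That call ended with either scaling (adjusted p = 0.110 and 0.109; 3 raised and 2 lowered with the kept probes) and without any 1 of control arrays 2, 4 and 6 or MWCNT arrays 1 and 4 (adjusted p up to 0.0714). Of 35 oxidative phosphorylation genes 2 rose and none fell (2 and none adjusted over the list alone; median 0.03, camera adjusted p = 0.129, 0.0425 without MWCNT array 6 and up to 0.234 without another array; called raised without both arrays with Y-linked signal, 0.0333, with sex as a covariate, 0.0278, and with no filter on dim probes, 0.0377), with Sdhd raised by 0.44 ± 0.10 (adjusted p = 0.00862). In contrast, 1 rose and 10 fell with scaling to the kept probes (median -0.10, adjusted p = 0.358), and with median scaling 4 rose and none fell (median 0.10). Of 19 glycolysis and hypoxia genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.04, camera adjusted p = 0.178, with fry's call of a move from no change at 0.0232; 3 rose without the arrays with Y-linked signal). With scaling to the kept probes 1 rose and 2 fell (median -0.10), and with median scaling 2 and none (0.10). Of 20 stress and immediate early genes none rose and 2 fell (none and none adjusted over the list alone; median 0.03, camera adjusted p = 0.795). With median scaling 2 of these rose and none fell (median 0.09), and scaling to the kept probes gave a median of -0.11.

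In all, camera called 21 of 29 lists raised and none lowered. The lists share members, so these calls are not independent. Of 19 granuloma and sarcoidosis genes 13 were also in another list, as were 10 of 21 monocyte-derived macrophage markers. With an estimated correlation 2 lists remained called, matrix proteases and monocyte-derived macrophage markers. The transcript Xist, which is made from the inactive X chromosome, lay at 11.36 ± 0.22 in controls and at 5.00 and 4.58 on MWCNT arrays 5 and 6. These 2 arrays alone carried signal of the Y-linked genes Eif2s3y (10.73 and 10.87, against 4.57 ± 0.07 in controls) and Kdm5d (7.69 and 8.02, against 4.68 ± 0.09). The Y-linked gene Uty did not set them apart, with 5 control and 4 MWCNT arrays detecting it (-0.16 ± 0.19, adjusted p = 0.644). Its other probes were detected on no array, so Uty cannot settle the sex of these animals. The loss of Xist together with signal of Eif2s3y and Kdm5d argues against female animals on these 2 arrays. Xist was detected on the other 10 arrays. Both arrays are in the MWCNT group, so what sets them apart is partly confounded with treatment. Without MWCNT arrays 5 and 6, 798 genes were raised, 420 lowered and 23 lists called, an alternative added after seeing the data. Of the raised and lowered genes above, 635 and 328 were shared. The direction of small changes rested on the scaling between arrays. Scaling each array to its median in place of quantile normalization moved the median log2 fold change of all features from -0.02 to 0.10, with 1357 genes raised and 126 lowered (91.5% raised, against 58.5%). Relative to that median, 765 were raised and 247 lowered. Scaling to the median of the kept probes, chosen after seeing the data, moved it to -0.10, with 679 raised and 1391 lowered (32.8% raised), or 953 and 449 relative to it.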

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

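The test of lymphocyte marker counts, the 3 tests on MWCNT array 5, the background tests of the lowered genes and the test of the lowered genes kept under median scaling were chosen only after the results they measure were seen. The background tests are the last of 4 forms tried, after a count of bright features, a bound compared by value and the same bound with a margin of 2 SE; those forms excluded background for more of the lowered features. Leaving out the arrays with Y-linked signal and scaling to the kept probes were also added after the data were seen.

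In each group of 6 arrays, the gap between the most extreme array and its neighbour was set against the group's whole range, and a ratio above 0.625 set that array apart. Chance sets apart about 1 in 20 groups, or 19 of the 380 examined, and 31 were set apart. MWCNT array 5 was the lowest in 12 of these and the highest in 2. It was lowest for the scores of matrix proteases (ratio 0.729) and macrophage fusion (0.746) and for the levels of Mmp12 (0.651), Il7r (0.638), Cd40 (0.626) and Mgl2 (0.643). It was also lowest for Il1r2 (0.786), Cxcl16 (0.660), Cxcr2 (0.712), F13a1 (0.637), Nlrc5 (0.685) and Marco (0.635), and highest for Apcdd1 (0.677) and H2-M10.1 (0.774), which fell on the other MWCNT arrays too. MWCNT array 1 was lowest for Fos (0.638) and MWCNT array 3 for Itgad (0.814).

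Among controls, array 1 was highest for the T and NK cell score (0.635), S100a9 (0.693), Trib3 (0.635), Irgm1 (0.646) and Myd88 (0.631), and lowest for Mgl2 (0.684) and Cd63 (0.659). Control array 2 was highest for the B and plasma cell score (0.653) and for Alas2, an enzyme of haem synthesis in red cell precursors (0.706). Control array 3 was highest for Cd163l1 (0.877) and lowest for C1qc (0.727) and C1qa (0.785). Control array 4 was highest for Jund (0.674), and control array 5 was lowest for the protease score (0.650) and Trbv13-2 (0.658). Signal of 2 Y-linked genes, whose probes no comparison uses, appeared on MWCNT arrays 5 and 6 above the level in controls: Eif2s3y at 10.73 and 10.87, and Kdm5d at 7.69 and 8.02. Uty, also Y-linked, did not set them apart: its kept probe was detected on 5 control and 4 MWCNT arrays and lay at 6.12 and 6.06 on these 2, below control array 4 (6.18). The other Uty probes were detected on no array, so Uty cannot settle the sex of these animals. The signal of Eif2s3y and Kdm5d, with Xist detected on the other 10 arrays only, argues against female animals on these 2.

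Transcripts of T and B cells rose in cells that the labels give as over 90% macrophages. The arrays with Y-linked signal do not account for this, since the T and NK cell median was 1.61 without them. Nor does the normalization, since the lowest median over 4 others was 0.45, with the list still called. A larger share of lymphocytes in the lavage and regulation of these genes within macrophages cannot be told apart here, since the 21 of 29 measured markers raised restate the pattern and the labels give no lymphocyte count. Cd2, the brightest of the T and NK cell markers not called, lay at 12.84 ± 0.11 in controls and 12.67 ± 0.06 with MWCNT. Such a baseline could hide a small share of T cells.

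MWCNT array 5 showed a smaller rise than the other MWCNT arrays: its median share of the raised response was 0.389, against 0.892 to 1.20 on the others, for genes called without the array in question. RNA of these controls mixed in at the missing 73.8% would give Xist a level of 10.93, and Xist lay at 5.00, below that by more than the control SD of 0.22. The 95th percentile of signal over background was lowest on MWCNT array 5 (16.2, against 16.9 to 21.3), which goes with compressed signal. Its share of the lowered response was 0.765, within the 0.712 to 0.972 of the others, which by the test's rule counts against compression. This share cannot decide on compression, or on a dose that shrinks both directions. For most lowered calls, scaling or background cannot be told apart from a true decrease. The sex of the animal may play a part, since MWCNT arrays 5 and 6, both with Y-linked signal, had the lowest shares (0.389 and 0.892). The exact two-sided permutation p was 0.0667, the smallest that 2 arrays against 4 allow, so sex and other differences between these animals cannot be told apart here.

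The number of lowered genes moved with the scaling: of the 538, 532 were still called when arrays were scaled to the kept probes, the bound set beforehand against scaling as the cause. That bound was wrong, because this scaling moves the median of all features to -0.10 and so favours lowered calls, while median scaling left 125 of the 538. Of the 538, 107 were lowered under all 5 other normalizations, among them Cidec, Krt79, H2-DMa, Tgfb2 and Il7. Of these 5, only median scaling works against lowered calls, since the others kept quantile scaling or favoured such calls. The 107 were picked for staying lowered, so this is no separate support. In its own test median scaling called 126 genes lowered, 125 of them among the 538. Falls thus remained under a scaling that works against them, so the scalings tried do not account for every lowered call. The median used there lay near background (1.08 to 1.11 times it on the arrays), so median scaling aligned dim probes. For the lowered genes outside the 107, scaling and a true decrease cannot be told apart. Background left in the signal was set against the largest fall that the whole range of array backgrounds (37.6) could give: 9 of 123 lowered features above the upper quartile of brightness, 13 of 411 between the quartiles and 0 of 244 below fell beyond it at an adjusted p under 0.05, which excludes background as the whole cause for those 22. Above the upper quartile the median log2 change was -0.31 against a median bound of 0.02, and all 123 exceeded the bound by 2 SE. Those features were picked as lowered calls, and with bounds this small a called fall passes by 2 SE almost by construction. As a set the 123 therefore cannot decide on background, and 114 did not pass singly. For these 114, and for the other 398 and 244, background and a true decrease cannot be told apart. Between the quartiles and below them, 230 and 0 exceeded the bound by 2 SE without allowing for their choice as lowered calls. Of the dimmest, 193 had a bound above every fall seen.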

How the results depend on the processing

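Leaving out the arrays with Y-linked signal, sex as a covariate, scaling to the kept probes and leaving out control array 1 with MWCNT array 5 were chosen after seeing the data; the other alternatives were planned. Of 157 named genes 98 kept their direction and side of the threshold under every alternative, as did 3 of 29 lists. A fold of at least 1.5 left 587 genes (471 raised, 116 lowered) and a fold of at least 2 left 283 (278 and 5), by construction. Median scaling gave 1357 raised and 126 lowered, and scaling to the kept probes 2070 changed, 1391 of them lowered; each shifts all genes. Probes detected on all 12 arrays gave 457 raised, since probes undetected on 1 array or more drop out. Among these are probes of the 180 raised genes detected on no control array. An estimated correlation left 2 lists. The estimate was 0.59 for B and plasma cell markers and 0.41 for T and NK cell markers, far above the preset 0.01. The preset camera p-values of such lists are therefore likely too small. Cathepsins and fibrosis genes lost their calls at estimates of 0.0058 and -0.0312, both below the preset value. A high estimate therefore does not account for every lost call, and the cause of these losses was not tested. Leaving out 1 array gave 1044 to 1293 changed genes, 635 to 811 raised, 386 to 507 lowered and 18 to 22 lists. Psap (-0.23) and Chil4 (-0.23) turned negative with scaling to the kept probes, as did the lysosome median (-0.10). Lyz2 (0.46) and Lyz1 (0.43) turned positive with the mean of each gene's probes, where 1 dimmer probe was called the opposite way; the cause was not tested. The replicate block gave 1120 changed genes (704 raised, 416 lowered) and 18 lists, without MHC class I, fibrosis and lung epithelium. The replicate numbers were not taken to pair the samples, since 2 of 6 pairs correlated at -0.01 and -0.18, though 4 lay over 0.1 and 6 of 12 arrays correlated best with their own number. The authors' values gave 759 raised, 574 lowered and 20 lists, sex as a covariate 831, 468 and 23, and leaving out control array 1 with MWCNT array 5 820, 468 and 21. A slide block was not run because the files used here name no slide. Low signal over background limits dim genes: of 23175 probes detected on no array 45 were called, 35 lowered and 10 raised. Of the 23175 probes, 10.2% had an unadjusted limma p under 0.05, more than chance gives.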

Other observations

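Genes were also grouped into 154 families by the stem of their symbol, a grouping chosen after the data were seen, and camera called 5. Among the Ccl chemokines, which draw in leukocytes, 11 of 13 rose (median 1.26, adjusted p = 5.28e-09; adjusted p = 0.658 with an estimated correlation), and the median was 1.36 with median scaling and 1.16 with scaling to the kept probes. Among the Mmp metalloproteinases 6 of 11 rose (median 0.38, adjusted p = 7.79e-06; adjusted p = 0.332 with an estimated correlation). Both families were called under either scaling.

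Among the Tspan tetraspanins, membrane organisers, Tspan33, Tspan3, Tspan32 and Tspan4 rose of 8 measured (median 0.26, adjusted p = 0.0284; adjusted p = 0.749 with an estimated correlation). Among the interferon-inducible Ifi genes 3 of 8 rose (median 0.47, adjusted p = 0.0246; adjusted p = 0.749 with an estimated correlation). The Tspan call ended under both scalings (adjusted p = 0.0545 and 0.0751) and the Ifi call with median scaling (0.0976). Of 202 zinc finger genes of the Zfp family 19 fell and 1 rose (median -0.09, adjusted p = 0.0246; adjusted p = 0.942 with an estimated correlation), but with median scaling the median turned to 0.07, 4 rose and 3 fell, and the call ended (0.424). It also ended with scaling to the kept probes (median -0.14, 2 raised and 28 lowered, adjusted p = 0.386).

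The real grouping was set against other splits of the 12 arrays into 6 and 6, with 100 of 462 drawn and the real one included. The 1297 changed genes, 759 raised genes and 538 lowered genes were each reached by 1 of the 100 splits, the real one, and the highest counts of the others were 272, 244 and 244. Chance can be excluded for these counts, but the splits cannot separate MWCNT from a batch that followed the groups. For the 21 lists, 2 of the 100 splits called as many, and the highest of the others was 21. That share lies under 0.05, the limit set beforehand for excluding chance, but wrong groupings come close to this count. The other split with 21 lists exchanged control array 6 with MWCNT array 6 and called 0 changed genes. The next highest count was 19, and 85 of the other splits called at least 1 list.

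A hypothesis set before it was tested was that the lymphocyte markers vary among the MWCNT animals together with other groups, and 3 correlations with the T and NK cell score were computed over the 6 MWCNT arrays, with exact two-sided permutation p-values. The monocyte-derived macrophage score had a Pearson r of 0.94 (p = 0.00417, adjusted 0.0125) and a Spearman rho of 0.94 (p = 0.0167, adjusted 0.05). The protease score had r = 0.86 (p = 0.0208, adjusted 0.0313) and rho = 0.89 (p = 0.0333, adjusted 0.05), and the B and plasma cell score r = 0.85 (p = 0.0333, adjusted 0.0333) and rho = 0.77 (p = 0.103, adjusted 0.103). Without MWCNT arrays 5 and 2, the farthest from the median, r was 0.81, 0.66 and 0.61 over 4 arrays, so the relations rest in part on those arrays. A dose that differed between animals could produce such a relation, as could differences in lymphocyte number, and the design cannot separate them. The 95th percentile of signal over background also differed among these arrays, from 16.2 on MWCNT array 5 to 20.3 on MWCNT array 1. Its part in these relations was not tested. The lowered response of MWCNT array 5 (0.765, against 0.712 to 0.972 on the others) cannot decide on dose. Most lowered calls cannot be told apart from scaling or background.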
